A study of Mus musculus with 2 samples.

How the data were processed

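Gene expression was measured on Affymetrix mouse arrays in cultured primary endothelial cells, the cells that line blood vessels, taken from mouse embryos at embryonic day 10.5. The embryos carried a floxed Snail1 allele, in which recognition sites for the Cre recombinase flank part of the gene. The cells were grown with 20% serum and endothelial growth factors, then infected with an adenovirus carrying either β-galactosidase (the WT group) or Cre (the Snail1 KO group) and left to recover for days, per the labels' protocols. Total RNA was extracted with Trizol and 250 ng were amplified into biotinylated aRNA, per the labels' protocols. The series holds 2 samples, 1 array in each group. The groups were taken from the sample titles.

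The deposited table gives 1 log2 expression value per probe set and array, made by the authors with RMA in the affy package, per the submitters' processing notes. RMA corrects background, applies quantile normalization between arrays and summarises the probes of each set on the log2 scale. Versions of these tools are not given in the sources used here. Quantile normalization forces the arrays towards 1 distribution of probe values, so a change of total mRNA output cannot be seen, and RMA compresses fold changes of dim probe sets. The sorted values of the 2 arrays differed by at most 0.133, and the values correlated across probe sets with a Pearson r of 0.99. No detection calls or scanner intensities were used here, so signal over background is not known for single probe sets. No column of the table was left unused.

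The table holds 45101 probe sets, of which 64 are array controls. GEO's platform annotation, in which a probe set can carry an old name, gave 1 gene symbol to 34945 of the others, several to 932 and none here to 9160. Probe sets with several symbols or none were left out of gene-level results, so their transcripts are unnamed here, not absent from the array. The Entrez identifiers of 34741 of the single-gene probe sets were found in a RefSeq table of assembly GRCm38.p6, which changed no symbol. List genes with an older symbol were matched through that table's synonyms. No genome coordinates were used.

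The log2 difference was the Snail1 KO value minus the WT value. Each of the 18193 genes was represented by its probe set with the highest mean over the 2 arrays. A gene was analysed further if that mean was above the 40th percentile of all probe sets other than controls, a log2 value of 3.97, which left 12874 genes. This filter removes dim genes and is not a test of detection. Genes were counted by size, at a 2-fold difference, which is 1 log2 unit.

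With 1 array per group there is no estimate of the variation between cultures, and no p-value, standard error or confidence interval is given. The number of arrays limits the precision. As yardsticks, the robust SD of the log2 difference over the analysed genes was 0.32 (0.25 to 0.36 across 20 bins of mean level), and the difference between 2 probe sets of 1 gene had an SD of 0.40 over 10436 probe sets. Both include probe error, and neither replaces replicate cultures.

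For each gene list, the median log2 difference of the members that passed the filter was ranked among the medians of 10000 random lists of the same size, drawn with replacement from genes in the same bins of mean level. A list was said to stand apart when it lay outside the central 95% of random lists. This describes the 2 arrays and is not a test between conditions, and genes of 1 pathway vary together, which widens the true spread. Before the data were examined, 27 lists were fixed. They covered Notch, Wnt, TGF-beta and BMP and VEGF signalling, endothelial subtypes, EMT, matrix, cell cycle, stress and inflammatory programmes, and markers of other cell types. Another 8 lists were written after the data had been seen. Lists with under 5 analysed members were given as values.

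Most genes named below followed a rule fixed before the data were examined. It took Snai1, the 12 genes with the largest difference in each direction whose analysed probe sets all had the same sign (clone and model names left out), the up to 4 members of each list with the largest absolute difference, and a short set of Notch, arterial, EMT and endothelial genes. Mt2, Cd14, Cd68, Ptprc, Tyrobp, Thy1, Dcn and Erap1 fall outside it and were chosen after their values were seen. The count by size and the list ranking were tested on simulated data with the levels of the 12874 genes. The simulated noise was normal, with the robust SD of these same arrays at each level, and genes did not vary together. The figures that follow hold for that setting and are not error rates of the real arrays. Of genes changed by 1.5 log2 units, 95% were found at 2-fold, against 100% of those changed by 2.5 units, and 15 of 12674 unchanged genes passed. Of 200 unchanged lists of 20 genes, 2.5% lay outside the central 95%, and all lists shifted by 0.5 log2 units were found.

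The alternatives were no filter, a filter at the 60th percentile, the mean of all probe sets of a gene, leaving out probe sets whose ID ends in _s_at or _x_at (which can bind several transcripts), centring on the median, removing the lowess trend with level (span 0.3), thresholds of 1.5-fold and 3-fold, and each list without its most changed member. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.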

Results

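Expression was profiled in endothelial cells cultured from mid-gestation mouse embryos, on 1 array of cells given a β-galactosidase adenovirus (WT) and 1 array of cells given a Cre adenovirus (Snail1 KO). Both arrays reported 45101 probe sets, with median log2 values of 4.66 for WT and 4.70 for Snail1 KO. The comparison asks which transcripts differ in embryonic endothelial cells given Cre to delete Snail1, a zinc finger transcription factor known for repressing epithelial genes. Each group received its own virus, and no array holds cells given Cre without a floxed Snail1. For every gene and list below, loss of Snail1 therefore cannot be told apart from an effect of the virus or of Cre. Each value comes from 1 array without a replicate, so differences are described by size and none was tested.

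Snai1 itself, measured by a single probe set, was 3.35-fold lower on the Snail1 KO array. Its log2 value was 5.33 on the WT array, at the 57.5th percentile of probe sets, and 3.59 on the Snail1 KO array, at the 33.3rd percentile and below the filter level of 3.97. The labels do not state which exons are floxed, so whether the probes lie inside the deleted part is not known. The array's control probe sets for the phage P1 Cre gene were at 2.69 to 3.83 on the WT array and at 11.87 to 12.86 on the Snail1 KO array. Cdh5, which encodes VE-cadherin, was at 11.34 in WT and 11.46 in Snail1 KO, and the adhesion molecule Pecam1 was at 10.18 and 10.22. The pan-endothelial list had a median difference of 0.05 over 28 genes, with Cldn5, a tight junction claudin, 2.11-fold higher, Cd34 3.07-fold lower and 26 members within 2-fold.

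**Figure D1:**
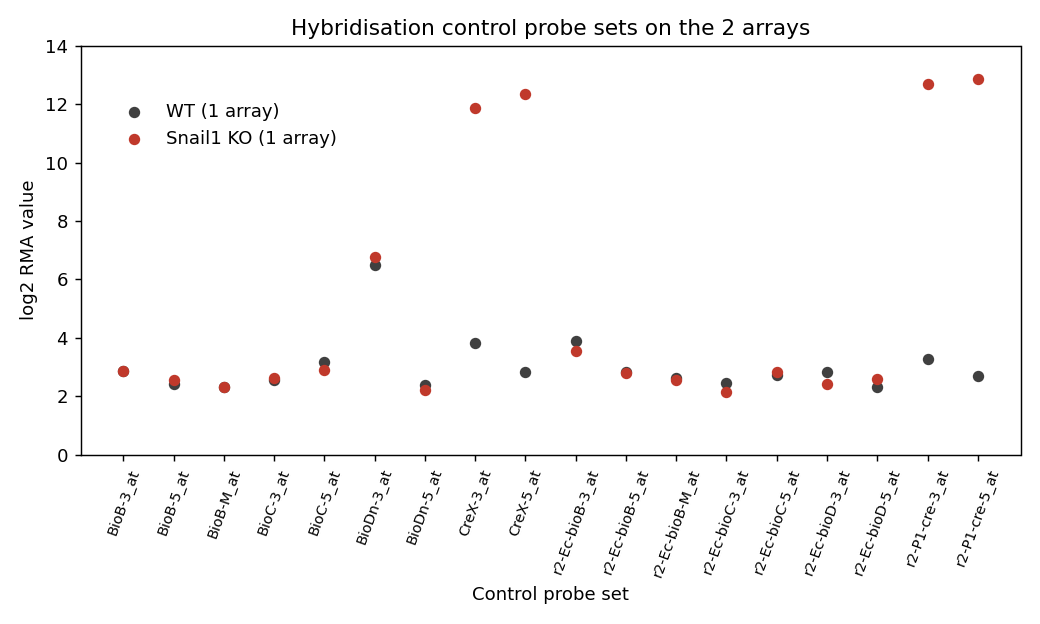
Log2 RMA value (vertical axis) of the Cre, bioB, bioC and bioD control probe sets (horizontal axis) on the WT array (dark points) and the Snail1 KO array (red points), 1 array each. The 4 Cre probe sets lie at 2.69 to 3.83 on the WT array and at 11.87 to 12.86 on the Snail1 KO array, while the 14 bioB, bioC and bioD probe sets differ by -0.42 to 0.27.

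Of 12874 genes analysed, 125 were at least 2-fold higher and 237 at least 2-fold lower on the Snail1 KO array, and 97.2% lay within 2-fold. Differences of at least 4-fold were found in 3 genes in the higher direction and in 54 genes in the lower. Among genes whose analysed probe sets all had the same sign, the largest positive differences were those of Mt1, a metallothionein (a log2 difference of 3.91, from 8.58 on the WT array to 12.49 on the Snail1 KO array), Cd36, a fatty acid and thrombospondin receptor (4.46-fold), and Cyfip2, a regulator of actin assembly (4.14-fold). Cracd, Fgl2, Rbp7, Tnxb, S1pr3, Serpinb11, Slc45a3, Reln and Gucy1b1 followed, between 3.71-fold for Cracd and 3.40-fold for Gucy1b1. These folds are of the brightest probe set, and other analysed probe sets differed by 0.47 and 3.08 for Cyfip2 and by 0.21 for Cracd. S1pr3, a sphingosine 1-phosphate receptor, was below the filter level on the WT array, with a log2 value of 3.41. The largest negative differences were those of Oasl2 (23.7-fold), the chemokines Cxcl10 (16.6-fold) and Ccl5 (a log2 difference of -3.47), and the interferon-inducible genes Ifi202b (8.93-fold) and Zbp1 (8.74-fold). Ptgs2, which encodes the prostaglandin synthase COX-2, Plscr2, Mndal, Cxcl12, Iigp1, Rsad2 and Tspan8 followed, between 8.44-fold for Ptgs2 and 7.01-fold for Tspan8, while the least changed of their probe sets differed by -0.46 for Cxcl12 and by -0.48 for Tspan8. Oasl2, Cxcl10 and Tspan8 were below the filter level on the Snail1 KO array, at 3.68, 3.74 and 3.75. Ifi202b and Mndal belong to a family of near-identical genes, and the arrays may not tell its members apart. Where a gene had several analysed probe sets, 48 of 56 genes that were 2-fold higher and 86 of 95 that were 2-fold lower had the same sign in all of them. Averaging all probe sets of a gene reduced the number of higher genes to 77.

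**Figure D2:**
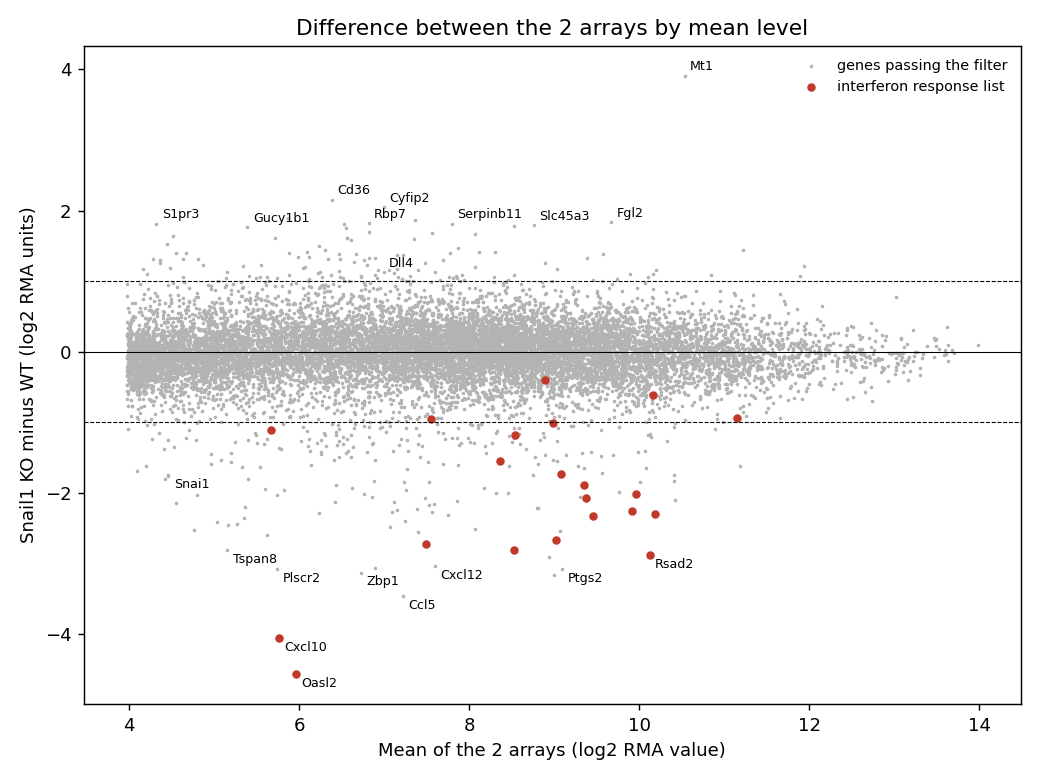
Snail1 KO minus WT in log2 RMA units (vertical axis) against the mean of the 2 arrays (horizontal axis) for the 12874 analysed genes (grey points), with the interferon response list in red and dashed lines at 2-fold. Below the lower line lie 237 genes and above the upper line 125, and 17 of the 21 red points are below the lower line.

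Interferon-stimulated genes were lower on the Snail1 KO array as a group. All 21 analysed members of the interferon list were lower, 17 of them by at least 2-fold, and the median difference was -2.01 log2 units, which is 4.04-fold lower. Beside Oasl2 and Cxcl10, the antiviral gene Rsad2 was at 11.57 in WT and 8.69 in Snail1 KO (7.36-fold) and Ifit3, an RNA-binding antiviral protein, at 9.93 and 7.12. The inflammatory and NF-kB list had a median of -0.86 over 18 genes, with 8 at least 2-fold lower and none 2-fold higher. Ccl7, a monocyte chemokine, was 4.82-fold lower and Tnfaip3, an inhibitor of NF-kB, 4.71-fold lower in its brightest probe set, while a further Tnfaip3 probe set differed by -0.21. Both medians lay below all 10000 random lists. The 2 lists together supplied 16 of the 54 genes that were at least 4-fold lower. Of the leukocyte markers, 11 were analysed and their median difference was -0.08, within the random lists. Coro1a, an actin-binding protein of blood cells, was 3.89-fold lower and the mannose receptor Mrc1 2.88-fold higher, from a WT value of 3.68, below the filter level.

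Notch pathway genes had a small positive median difference of 0.17 over 28 members, at the 98.7th percentile of random lists. Of these, 2 were at least 2-fold higher, 1 was 2-fold lower and 25 were within 2-fold. Dtx1, a ubiquitin ligase of the Notch pathway, was at 7.13 in WT and 8.60 in Snail1 KO (2.77-fold higher) and the Notch ligand Dll4 at 6.43 and 7.56 (2.19-fold higher), with a further Dll4 probe set higher by 0.83. The target gene Hey1 was 1.57-fold higher, Notch1 1.32-fold and Hes1 1.18-fold. The receptor Notch4 was 2.44-fold lower in its brightest probe set, with another at -0.49, and the ligand Jag1 differed by -0.12 in its brightest probe set and by up to 0.75 in another. Hey2 was at 2.37 and 2.77, below the filter level on both arrays. Without Dtx1 the Notch list lay within the central 95% of random lists, at the 96.7th percentile, and so it did without the probe sets that can bind several transcripts, at the 95.6th.

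Endothelial subtype genes differed in both directions. The arterial list, which shares Dll4, Hey1, Notch1, Notch4 and Jag1 with the Notch list, had a median of 0.22 over 17 genes, with 9 higher and 8 lower. Its kinase Bmx was 1.90-fold higher, from a dim 4.49 to 5.42, and the VEGF co-receptor Nrp1 was 2.06-fold lower in its brightest probe set and lower in the other 3, the least changed at -0.54. Efnb2, the arterial ephrin, differed by -0.53 in its brightest probe set, and its probe sets ranged from -0.53 to 0.99. With the filter at the 60th percentile the arterial median had the opposite sign, at -0.046, and lay at the 27.9th percentile. The venous and lymphatic list had a median of 0.46 over 12 genes, above all 10000 random lists, with 11 of 12 members higher and 1 past 2-fold. Prox1, the transcription factor that specifies lymphatic endothelium, was 2.08-fold higher, with values of 9.57 and 10.63, and all 3 of its probe sets differed by at least 1.02. The scavenger receptor Stab1 was 1.75-fold higher, the venous receptor Ephb4 1.62-fold and the VEGF-C receptor Flt4 1.59-fold, with a further Flt4 probe set at 0.24.

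**Figure D3:**
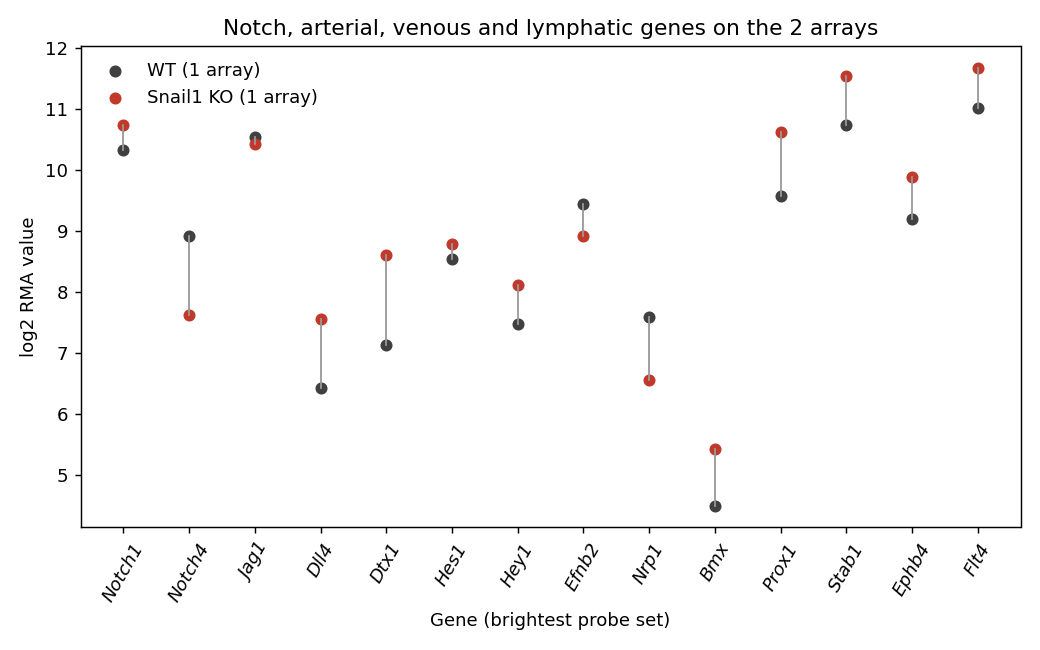
Log2 RMA value (vertical axis) of the brightest probe set of selected Notch, arterial, venous and lymphatic genes (horizontal axis) on the WT array (dark points) and the Snail1 KO array (red points), 1 array each, joined by a grey line per gene. Dll4, Dtx1, Hey1, Prox1, Stab1, Ephb4 and Flt4 lie higher on the Snail1 KO array, and Notch4, Nrp1 and Efnb2 lie lower.

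The list of sprouting tip cell genes had a median of -0.40 over 17 genes, below all 10000 random lists, with 11 lower and 6 higher on the Snail1 KO array. Esm1, a secreted proteoglycan of tip cells, was at 8.68 in WT and 6.13 in Snail1 KO (5.84-fold lower), the IGF-binding protein Igfbp3 was 2.81-fold lower and the peptide ligand Apln 2.77-fold lower. Dll4, a member of this list too, was the 1 gene of it past 2-fold in the other direction. Without Esm1 the median was -0.23, at the 1.07th percentile. VEGF and angiopoietin ligands and receptors had a median of 0.41 over 14 genes, above all 10000 random lists, but a mean of 0.078. Of these, 9 were higher, none by 2-fold, and 5 lower, with Angptl4 and Nrp1 past 2-fold. Vegfa was 1.91-fold higher in its brightest probe set and differed by 0.02 in the other. Flt1, a VEGF receptor, was 1.67-fold lower in its brightest probe set, with the least changed of its 4 at -0.25, and Angptl4, an inhibitor of lipoprotein lipase, was lower by a log2 difference of -1.58, although its other probe set, below the filter level on both arrays, gave 0.062.

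The list of mesenchymal genes had a median of -0.52 over 20 genes, below all 10000 random lists. Of these, 15 were lower, 4 of them by at least 2-fold, and 5 higher, with 16 within 2-fold. Tagln, an actin-binding protein of smooth muscle, was at 10.35 in WT and 7.80 in Snail1 KO (5.83-fold lower), Acta2, smooth muscle actin, was 3.60-fold lower, Ccn1, a matricellular protein, 3.37-fold lower and the collagen gene Col5a2 3.08-fold lower. The list of pericyte and smooth muscle markers, which shares Tagln and Acta2 with the mesenchymal list, had a median of -0.40 over 11 genes at the 0.11th percentile, with 8 lower and 3 higher. Its 6 analysed contractile genes had a median of -1.07, among them Myl9, a myosin light chain, 2.51-fold lower, and Cnn1, calponin, 1.75-fold lower. Lmod1 and Des, also counted among the 6, differed by -0.40 and 0.007. This split of the list was made after the data had been seen. The 8 markers without a contractile role, dim ones included, had a median of -0.20. The fibroblast markers had a median of 0.12 over 11 genes, within the random lists. Among them Col3a1 was at 7.33 in WT and 6.33 in Snail1 KO, while Fbln2 was 1.52-fold higher and Igf1 differed by 0.56 in its brightest probe set and by 0.48 to 1.56 over its 4.

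Apart from Snai1, the list of EMT transcription factors had 1 gene past 2-fold, Zeb2, which was 2.58-fold lower in its brightest probe set and differed by -0.02 in another. Snai2 and Zeb1, of the same list, differed by -0.25 and 0.06, with another Zeb1 probe set at 0.96. Hmga2, a chromatin protein, was 1.90-fold lower, and Twist1 was below the filter level on both arrays, at 3.62 and 3.44. The list median was -0.05 over 9 genes. Epithelial genes had a median of -0.11 over 18 members, within the random lists, with none 2-fold higher. With the filter at the 60th percentile that median was 0.32, at the 98.1st percentile. The keratins Krt19 and Krt18 were 2.59-fold and 2.45-fold lower, the polarity gene Pard6b and the splicing factor Esrp2 were 1.94-fold and 1.78-fold higher, with a further Esrp2 probe set at 0.36 and Pard6b at 3.66 on the WT array, below the filter level, and E-cadherin, Cdh1, was at 2.59 and 2.51, below the filter level on both arrays.

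Immediate early genes had a median of -0.27 over 15 members, at the 0.73rd percentile, with Egr1 2.89-fold, Nr4a1 2.74-fold and Atf3 2.25-fold lower, and Fosl1 1.91-fold lower. Without Egr1 the median was at the 3.53rd percentile, inside the random lists. The remaining ranked lists lay within the central 95% of random lists. Matrix proteases and inhibitors had a median of -0.07 over 17 genes, in which Timp1, a metalloproteinase inhibitor, was 2.68-fold lower, Mmp11 was 2.08-fold higher and Mmp14, which encodes the membrane protease MT1-MMP, differed by -0.27. Basement membrane genes had a median of -0.19 over 15 genes with none past 2-fold, and Lama5 differed by 0.64 and Lamb1 by -0.62 in its brightest probe set, with another at 0.12. TGF-beta and BMP genes had a median of -0.013 and a mean of 0.016 over 25 genes, with Tgfbr3 and Tgfb3 2.02-fold and 2.01-fold higher. In the Wnt list, with a median of 0.085 and a mean of -0.086 over 19 genes, the inhibitor Sfrp1 was 5.28-fold lower and lower in all 5 of its probe sets, the least changed at -0.79, the target Sp5 was 3.71-fold lower, and the feedback inhibitor Nkd1 was 2.05-fold higher in its brightest probe set, with another at 0.23.

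None of the 31 cell cycle genes and none of the 20 p53 targets was past 2-fold in its brightest probe set, with medians of -0.11 and 0.11. The mitotic kinase Plk1 was 1.69-fold lower. Sesn1, a stress-responsive sestrin, was 1.98-fold higher in its brightest probe set and differed by 0.46 and 1.21 in its other analysed ones. Hypoxia and glycolysis genes had a median of -0.16 over 21 genes, and the glucose transporter Slc2a1 was 2.66-fold lower. Cholesterol synthesis genes had a median of 0.20 over 16 genes, at the 97.2nd percentile (98.6th with the mean of all probe sets of a gene), with 14 of 16 higher and none past 2-fold. Of markers of other tissues, the erythroid and blood progenitor list had a median of -0.13 over 9 genes, with Myb 2.65-fold higher. The neural list had a median of -0.07 over 7 genes, of which the filter at the 60th percentile left 1, at -0.73. The liver, heart and skeletal muscle list had a median of -0.10 over 6 genes, which was positive under 4 alternatives, up to 0.16 over 3 genes. The Y-linked gene Eif2s3y was at 8.37 and 8.36, and Xist, which is transcribed from the inactive X chromosome, at 4.16 and 3.96. As a sign of RNA quality, the 3' probe set of Actb exceeded its 5' probe set by 0.30 log2 units on the WT array and by 0.34 on the Snail1 KO array, and that of Gapdh by 0.02 and 0.08. Of the 26 ranked lists, 10 lay outside the central 95% of random lists, against 1.3 for lists of independent genes. Several of the 10 share members, such as Flt4 in the venous and lymphatic, tip cell and VEGF lists, so they are not 10 separate results.

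**Figure D4:**
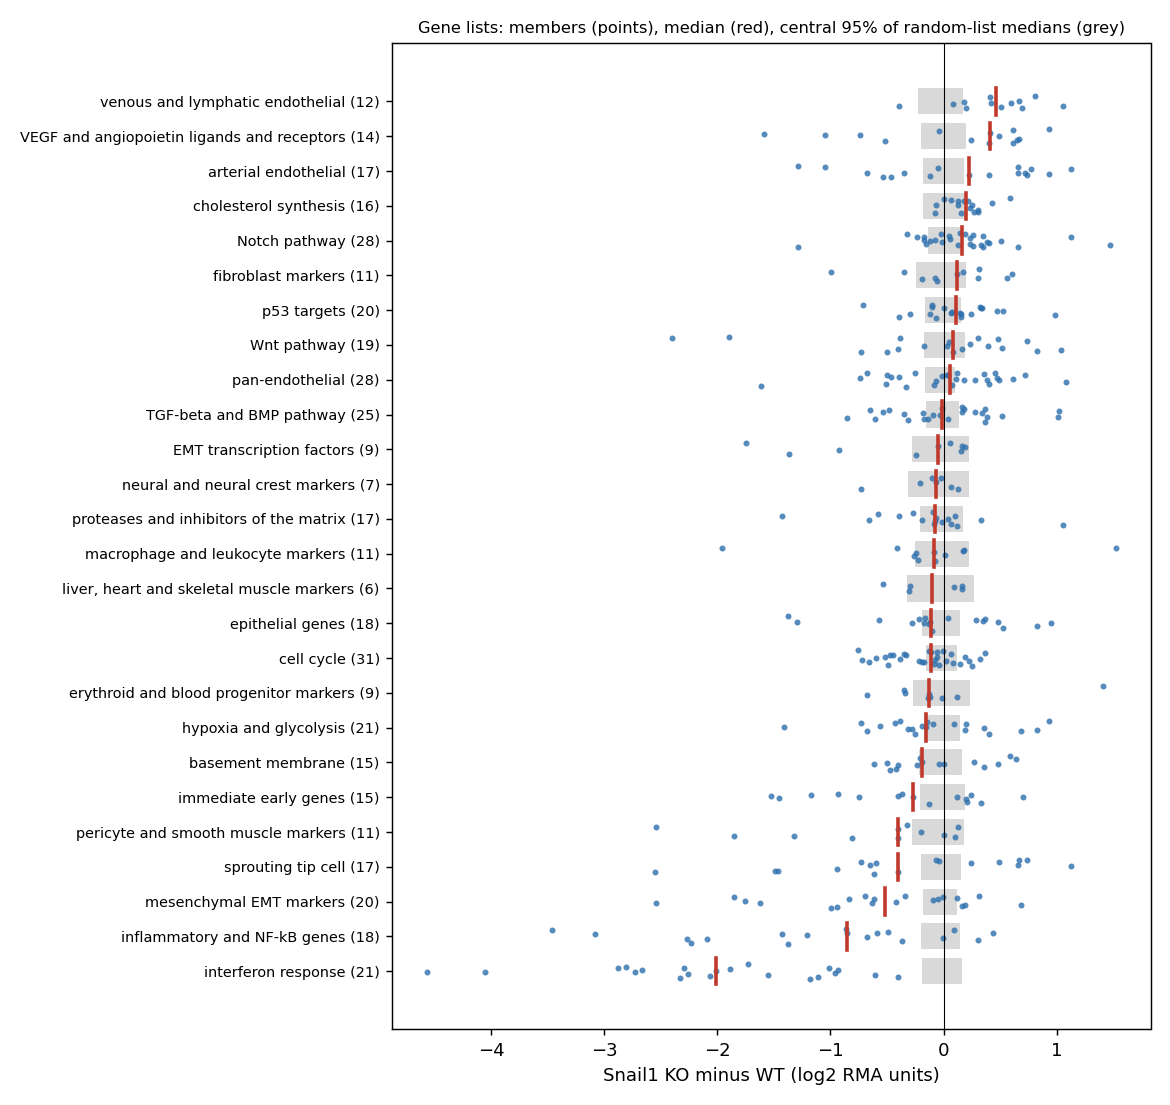
Snail1 KO minus WT in log2 RMA units (horizontal axis) for the analysed members (blue points, spread vertically only for visibility) of the 26 ranked gene lists, with the number of members in brackets, the list median (red bar) and the central 95% of medians of 10000 random lists (grey). The interferon list has the lowest median, -2.01, and the venous and lymphatic list the highest, 0.46.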

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

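The tests in this part were chosen after the results had been seen. The 4 control probe sets for the phage P1 Cre gene, which belong to no comparison of genes, were far brighter on the Snail1 KO array than on the WT array. The log2 differences were 8.04 and 9.52 for the older pair and 9.44 and 10.17 for the newer pair, but the WT values lay below the filter level, where background was not measured, so these sizes are not exact. The same array held the largest positive difference among the analysed genes, that of Mt1, at 3.91 and 4.59 in its 2 probe sets.

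A hybridisation control mix would bring bioB, bioC and bioD transcripts along with Cre, but their 14 probe sets had a median difference of -0.029 and a highest of 0.27, which argues against the mix. Only the Snail1 KO cells were given a Cre adenovirus, so a transcript made from it is the source of Cre that the design names. The differences, of which 8.04 is the smallest, are the observation itself, so no separate value tests that source. For Mt1, induction of metal response genes would raise its neighbour Mt2 as well, which differed by -0.24 and argues against that explanation. Some Cre cassettes end in the polyadenylation region of mouse Mt1, so a viral transcript may account for the Mt1 signal, with 3.91 as the smaller of its differences, but neither probe nor vector sequences were used here. That stays open, as does an effect of Snail1 loss on Mt1, which was not tested.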

How the results depend on the processing

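Leaving out an array was not possible because each group holds 1, and Snai1 has no other probe set to compare. Counts depended on the size threshold by construction: 652 genes were higher and 783 lower at 1.5-fold, and 23 and 90 at 3-fold. With the mean of all probe sets, 77 genes were 2-fold higher. The other counts, including those of genes whose probe sets all had the same sign, an alternative chosen after seeing the data, stayed within 1.5 times. Of the 10 lists outside the central 95% of random lists, 6 were there on the same side under all 7 alternatives. The Notch median was 0.25 with the mean of all probe sets. The arterial median reversed to -0.046 with the filter at the 60th percentile, which removed its 2 dimmest members, both higher, and left 15. The tip cell median was -0.23 without Esm1. The mesenchymal median was -0.42 without a filter and without Tagln, -0.62 with the stricter filter, -0.39 with the mean of all probe sets and -0.34 without _s_at and _x_at probe sets. The interferon median was -1.92 with the mean of all probe sets. The inflammatory median was -0.75 without a filter, -1.32 with the stricter filter and -1.15 with the mean of all probe sets. The pericyte and smooth muscle median was -1.59 with the stricter filter, which left 4 members, too few to rank. Epithelial genes lay above the central 95% of random lists with the stricter filter, at the 98.1st percentile. Cholesterol synthesis genes did so with the mean of all probe sets, at the 98.6th percentile. Of 602 values of named genes under alternatives, 43 moved by more than the robust SD at their level and 1, that of Angptl4, was classed as reversed. It went to 0.062 without _s_at and _x_at probe sets, which left Angptl4 a probe set below the filter level. Other genes had probe sets of both signs, among them Efnb2 (-0.53 to 0.99) and Jag1 (-0.12 to 0.75), so their sign depends on the probe sets used. The lowess trend ran from -0.08 to 0.04, so centring and detrending moved little. Values near the filter level of 3.97 have no measured background. The SD of 0.32 over genes can hold real differences as well as noise. It is not a limit of noise, which can exceed 1 SD. With 1 array per group, differences near or below it cannot be told from noise, and larger ones cannot be told from variation between cultures.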

Other observations

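The 8 lists in this part were chosen after the data had been seen, and so were the tests on the trend with signal level, fibroblasts, pericytes, leukocytes and the viruses. The test of actin and SRF genes was set before its result was seen. Of the 8 lists 5 lay outside the central 95% of random lists, against 0.4 for lists of independent genes, but values of several members had prompted them, so they are not independent evidence. Lymphatic endothelial genes were higher on the Snail1 KO array, with a median difference of 0.67 over 13 genes and 12 of 13 higher, above all 10000 random lists. Reln, a secreted glycoprotein of lymphatic vessels, was 3.43-fold higher, Itga9, an integrin of lymphatic valves, 2.52-fold in its brightest probe set with another at 0.20, Prox1 2.08-fold, and Maf, a transcription factor, 1.95-fold, with the lowest of its 6 probe sets at 0.07. Reln, Prox1, Flt4, Lyve1, Pdpn, Nrp2, Foxc2 and Sox18 had been seen before the list was written, and 5 of these (Prox1, Flt4, Lyve1, Pdpn and Nrp2) are in the venous and lymphatic list too. Guidance genes (semaphorins, ephrins, netrins and their receptors) had a median of 0.17 over 20 genes, at the 97.6th percentile. Sema4d was 2.82-fold higher in its brightest probe set, with a further one at -0.35, and Ntn1, a netrin, was at 5.14 in WT and 6.14 in Snail1 KO, while Sema3c was 2.22-fold, to 3.78 on the Snail1 KO array, below the filter level, and Slit2, a secreted repellent, 2.03-fold lower, with a further Slit2 probe set at -0.55. Fatty acid uptake genes had a median of 0.15 over 12 genes, within the random lists, although Cd36 and Rbp7, a retinol-binding protein, which prompted the list, were 4.46-fold and 3.54-fold higher.

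Related interferon-inducible genes were lower as well. All 8 analysed guanylate binding and IRG genes were at least 2-fold lower, with a median of -1.55, among them Iigp1 (7.49-fold) and Gbp6 (4.03-fold), but Gbp2 and Gbp3 belong to the interferon list too, and they and Iigp1 had been seen before. All 13 analysed MHC class I presentation genes were lower in their brightest probe set, with a median of -0.43 at the 0.02nd percentile, while further probe sets of Tapbp and Erap1 differed by 0.39 and 0.056, and the immunoproteasome subunit Psmb8 was 2.41-fold lower. YAP targets had a median of -0.39 over 16 genes, below all 10000 random lists, with Ankrd1, a nuclear ankyrin protein, 4.17-fold lower and F3, tissue factor, 3.08-fold lower, to 3.39 on the Snail1 KO array, below the filter level. Ccn1, Ccn2 and Tgfb2 of that list had been seen before, and the first pair belongs to the mesenchymal list too. Metal and oxidative response genes without Mt1 had a median of 0.14 over 11 genes, within the random lists, and Nqo1, a quinone reductase, was 1.81-fold higher.

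The trend of differences over signal level ran from -0.082 to 0.039, which argues against it as the source of an interferon median of -2.01 (the test set beforehand, removing the trend, gave -1.99 and could hardly move it). The leukocyte markers had a median of -0.085 with an SD of 0.80 over 11 genes, far from -2.01. Of the brightest, Cd14, Cd68 and Lyz1 differed by 0.17, -0.075 and -0.41. Coro1a differed by -1.96, close to the interferon median, and by -1.64 in its other analysed probe set. Csf1r and Spi1 were dim on the WT array, at 4.91 and 4.63, and Ptprc and Tyrobp, at 2.96 and 3.95, were below the filter level. Such dim markers could hardly fall. The values weigh against loss of leukocytes from the Snail1 KO culture but do not exclude it. A different response to the 2 viruses cannot be told apart from an effect of Snail1 loss, because the series holds 0 arrays outside the WT and Snail1 KO groups and each group received its own virus. Loss of Snail1 is the difference the design names, and it stays open and untested.

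The lower contractile genes (Tagln, Acta2, Myl9 and Cnn1 among them) could come from fewer contaminating cells. Fibroblast markers had a median difference of 0.12 with an SD of 0.45 over 11 genes, against a contractile median of -1.07. The brightest, Thy1 and Dcn, differed by -0.062 and 0.17, while Col3a1 differed by -0.998. Pdgfra and Lum were at 3.76 and 3.16 on the WT array, below the filter level, and could hardly fall. The values weigh against a loss of fibroblasts but do not exclude it. The 8 mural markers without a contractile role had a median of -0.20, but a median WT value of 4.37, below the 4.66 of all probe sets, so fewer pericytes or smooth muscle cells stay open. Lower output of actin cytoskeleton and SRF target genes within the endothelial cells is a further hypothesis, tested with a list written before its values were seen. Of its 22 genes 19 were lower, Fhl2 by 2.59-fold and Tpm2 by 2.08-fold, but the median of -0.18 was at the 2.63rd percentile and missed the bound of 2.5 set beforehand, so this stays open, as does an effect of Snail1 loss.

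Where a gene had several analysed probe sets, 173 of the 10436 dimmer ones differed by over 1 log2 unit upward from the brightest and 52 downward, with a median of 0.04. Of 3712 analysed probe sets with several gene symbols or none here, 66 were at least 2-fold higher and 50 at least 2-fold lower on the Snail1 KO array.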
